A study of Arabidopsis thaliana with 36 samples.

How the data were processed

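The series measured poly-A RNA of Arabidopsis thaliana roots in 36 libraries: 0 min on 1 mM KNO3, and 15, 45, 90 and 180 min after a move to fresh 1 mM or 10 mM KNO3. Plants were kept 2 days at 4 °C, then grown at 22 °C with 16 h light and 8 h dark, per the labels' protocols. Libraries were made by the BrAD-seq digital gene expression method, per the labels' protocols. The authors deposited raw counts of reads per gene identifier, 1 table per library, with no normalization. FastQC, Bowtie2, SAMtools and HTSeq are named with genome build TAIR10, per the submitters' processing notes, and their versions, settings, annotation and use of strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the tandem glutaredoxins, can therefore not be told apart with certainty. Each table held 32833 identifiers and 0 summary lines, and no column was left without a sample. Of the identifiers, 32548 matched a RefSeq gene table for assembly TAIR10.1, which was used for names only, since the builds bear different names. For the same reason no coordinates are given.

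Groups were taken from the labels, and the batch label of each library gave its replicate number. Each group has 4 libraries. Replicates joined their own 2 plates per time point, so they are separate plates, but the labels do not say that batches were grown as separate cultures, and p-values measure the spread between these samples. The chi-square check over 54 replicate pairs found no library deposited more than once within a group, and pairs across groups were not compared. The numbers pair samples across groups because the labels name a batch: deviations of same-numbered libraries from their group means correlated at -0.014 to 0.442, 27 of 32 above 0.1, and 28 of 32 libraries correlated best with their own number.

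The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM scaling, filterByExpr over the 9 groups, a quasi-likelihood fit of all 36 libraries with 1 coefficient per group and no block, two-sided, at a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. The 8 comparisons were 10 mM against 1 mM at each time and 1 mM at each time against 0 min, plus a joint test of the 4 concentration differences and a test that they differ between times. Adjustment was over 18768 genes tested within each comparison. The biological coefficient of variation was 17%, and 12.1% with the batch as a block. Gene lists, 25 with 348 members of which 314 were measured, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 25 lists per comparison. No gene was in more than 1 list. In 19 members the identifier had no symbol in the reference, and these genes are printed by identifier. Over the 200 list tests, median, mean and test differed in sign in 31, of which 0 were called. Of 11 calls for 10 mM against 1 mM, 1 held with an estimated correlation (jasmonate at 15 min), and of 31 calls against 0 min, 24 did. Comparisons against 0 min share the same 4 libraries, so no overlap between them is reported.

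Lists, comparisons and the rule for named genes were fixed before the data were examined. For 10 mM against 1 mM the rule takes up to 6 called genes with the largest and 6 with the smallest fold change, with a mean of at least 1 log2 CPM and 1 direction in all 4 batches, up to 4 called members per list, and 13 genes whatever their result (NIA1, NIR1, NRT2.1, NPF6.3, HRS1, LBD37, NRT2.5, GATA23, LBD16, LBD29, ARF7, ARF19 and IAA14). Against 0 min it takes 4 and 4 and up to 3 per list, and for the test of differing effects the 6 smallest p-values. Members of lists in 10 mM against 1 mM outside those 13, and genes called only with a block or by DESeq2, were chosen after their values were seen.

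Alternatives were RLE scaling, no filter beyond a total above 0 (25304 genes), DESeq2 1.42.0, the batch as a replicate block, only the 8 libraries compared, and leaving out each library and each batch. After the data were seen, an average over the 4 times, list tests without members lacking a symbol, an estimated correlation in the blocked fit, and fits without replicate 4 of 1 mM at 45 min were added. On simulated counts of 18681 genes built from these libraries, the test at 90 min recovered 18.2% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 90.9% of those changed 4-fold, and with the block 48.5%, 83.6% and 95.5%, with 1 false call without and 15 with the block. In the same simulation 20 of 20 lists shifted by 0.3 were called, and 1 of 20 unshifted lists was. Genes were drawn independently there, so this does not measure false calls for lists whose members vary together. At 90 min 66, 67 and 66 genes were changed 1.5-, 2- and 4-fold, beside the 20 shifted lists. The adjusted threshold eases as more genes change, so these shares can overstate what is found where few genes change. A fold against 0 reads is a lower bound from 3 counts over the group, a fold against 1 to 3 reads has a 95% counting interval, and both cover counting error only.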

Results

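RNA was profiled in roots of 7-day-old Arabidopsis thaliana seedlings (ecotype Col-0) that had grown on mesh over medium with 1 mM KNO3 and were moved, 2 h after dawn, to fresh medium with 1 mM or 10 mM KNO3. Roots were frozen 15, 45, 90 and 180 min after the move. For the 0 min group the mesh was lifted and set back on its own plate, so those roots were handled but met no fresh medium. The 36 libraries form 9 groups of 4, with 1 library per group from each of 4 batches, here called replicates 1 to 4. Each replicate joined 2 plates per time point, and the labels call the replicates biological, without saying how the batches were sown. They were BrAD-seq libraries, a 3' digital gene expression method in which reads come from the 3' ends of poly-A transcripts. Total counts ran from 1376404 to 7512410 per library (median 5126926), and 18675 to 21692 genes had a count. Replicate 1 was the shallowest batch, with a median total of 2155735, against 4657127, 6246828 and 6446532 for replicates 2, 3 and 4. Replicate 4 of 1 mM at 45 min had the lowest total of all, and its median correlation with its group mates, on log2 CPM across genes, was 0.909, while the next lowest of the 36 libraries was 0.942. Across the 54 pairs of replicates within groups, chi-square per degree of freedom ran from 2.69 to 12.4, so no pair agreed within sampling noise and every library counted as 1 sample. Values are log2 fold changes ± SE from edgeR with 4 libraries per group unless stated otherwise. Each SE was derived as the size of the log2 fold change over the square root of its F statistic. It is therefore approximate, as are the confidence intervals built from it.

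By its title, the series addresses the short-term response of roots to nitrogen supply and the early steps of lateral root formation. The comparison of 1 mM with 0 min asks which transcripts differed after a move to a fresh plate of the same medium. Those groups also differ in handling and in time of day. The comparison of 10 mM with 1 mM at a shared time asks which transcripts differed with the higher KNO3 supply after the same move. Potassium was 10 mM and 1 mM along with nitrate, as far as the labels describe the media.

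Touch, wound and jasmonate transcripts rose steeply within 15 min of the move to a fresh 1 mM plate. TCH4 (AT5G57560), a cell wall enzyme gene named for its response to touch, went from 1.97 ± 0.598 CPM (mean ± SD, n = 4) at 0 min to 69.7 ± 9.57 CPM, a log2 fold change of 5.17 ± 0.34 (adjusted p = 5.95e-15). RRTF1 (AT4G34410), a redox-responsive transcription factor, rose by 7.56 ± 0.43 (adjusted p = 1.35e-16), from 0.739 ± 0.649 CPM, and BHLH92 (AT5G43650) rose by 6.06 ± 0.57. Of the 17 measured genes of the touch and wound list, 16 rose (17 adjusted over the list alone), with ERF13 (AT2G44840) at 5.54 ± 0.40 and WRKY40 (AT1G80840) at 4.97 ± 0.36. All 9 measured genes of the jasmonate list rose (9 adjusted over the list alone), with a median of 4.02 (4.02 with JAZ8 at its lower bound). Among them JAZ8 (AT1G30135), which encodes a repressor of jasmonate signalling, had 166 reads at 15 min and 0 at 0 min, at least 53.9-fold higher against a floor of 3 counts over the group. That bound was 35.8 and 33.5 without replicate 4 or 3 at 0 min, and 29.8 and 34.1 without batch 3 or 4. LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, had 412 reads against 3, a ratio of 134 (95% counting interval 45.4 to 651). The ratio was 88.8 and 249 without replicate 4 or 3 at 0 min and 242 without batch 3. JAZ7 (AT2G34600) rose by 4.66 ± 0.32. The camera test gave an adjusted p of 9.01e-79 for the touch and wound list (5.12e-10 with an estimated correlation) and 1.16e-70 for the jasmonate list (1.96e-09 with an estimated correlation).

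Other groups had fewer called genes at 15 min. Type-A response regulators, which are induced by cytokinin and dampen its signal, fell as a list (median -0.64, adjusted p = 2.38e-06). Of the 10 measured, 5 fell (7 adjusted over the list alone), including ARR6 (AT5G62920) at -0.99 ± 0.19. Morning clock genes fell as a list (median -0.66, adjusted p = 3.36e-05), with 5 of 9 called (6 adjusted over the list alone): RVE1 (AT5G17300) was at -0.91 ± 0.27 and CCA1 (AT2G46830), a core clock repressor that peaks near dawn, at -0.69 ± 0.14. RVE1 lost its call when replicate 1 or 2 at 0 min (adjusted p = 0.123 and 0.0679) or replicate 3 or 4 at 15 min (0.0838 and 0.107) was left out, and without any 1 of batches 1 to 4 (0.201, 0.0654, 0.0959 and 0.0524). In the nitrate response regulator list, 6 of 24 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0245, and adjusted p = 0.334 with an estimated correlation). bZIP1 (AT5G49450) was at 1.72 ± 0.52 there and AT1G25550, a NIGT1-type repressor of nitrate-responsive genes, at 1.37 ± 0.17. Leaving out any 1 library at 0 min, replicates 1 to 4 in order, ended the call of bZIP1 (adjusted p = 0.061, 0.105, 0.0573 and 0.0585), as did leaving out replicate 3 or 4 at 15 min (0.086 and 0.257), or batch 1, 3 or 4 (0.0749, 0.189 and 0.281). Without the genes that have no symbol in the reference the regulator list was not called (adjusted p = 0.222). None of the 12 genes for nitrate reduction and reducing power was called by edgeR (3 rose adjusted over the list alone), and all 12 had positive values, with a median of 0.31. That list passed camera at adjusted p = 0.0253 but not with an estimated correlation (adjusted p = 0.638). The low-nitrogen list had 2 of 10 genes lower (3 adjusted over the list alone) and was not called (adjusted p = 0.0513), while it was with the batch as a block (adjusted p = 0.0396), with no filter on low counts (0.0355) and without replicate 4 of 1 mM at 45 min (0.04). Outside these lists' calls, MYB77 (AT3G50060) of the lateral root initiation list rose by 2.66 ± 0.32 and the auxin-conjugating GH3.17 (AT1G28130) fell by 1.19 ± 0.14. CYP718 (AT2G42850) fell by 2.03 ± 0.45. In all, edgeR called 1298 of 18768 genes, 1021 higher and 277 lower.

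Nitrate assimilation transcripts were higher at 45 min than at 0 min. Of the 12 genes for nitrate reduction and reducing power, 10 rose (11 adjusted over the list alone), with a median of 0.60: NIA1 (AT1G77760), a nitrate reductase, went from 117 ± 13.2 to 269 ± 85.5 CPM (1.21 ± 0.21, adjusted p = 0.000102), NIR1 (AT2G15620), the nitrite reductase, rose by 0.97 ± 0.15 and G6PD3 (AT1G24280) by 0.82 ± 0.19. Among the 24 nitrate response regulators 9 rose (11 rose and 2 fell adjusted over the list alone), with BT1 (AT5G63160) at 2.61 ± 0.37 (1.95 without replicate 1 at 45 min and 1.99 without batch 1) and BT2 (AT3G48360) at 2.28 ± 0.39. The low-nitrogen list fell, with 3 of 10 genes called (4 adjusted over the list alone), among them the glutaredoxin gene AT1G06830 at -1.98 ± 0.29 and GDH3 (AT3G03910) at -1.04 ± 0.21. Camera gave adjusted p = 9.75e-11, 8.81e-08 and 0.000271 for these 3 lists in turn, and 0.0079, 0.00646 and 0.00646 with an estimated correlation. In the ammonium assimilation list, which missed the threshold (adjusted p = 0.0636; 0.03 with the batch as a block), 3 of 10 genes rose and 1 fell, the same numbers adjusted over the list alone. ASN1 (AT3G47340), an asparagine synthetase, was at 1.76 ± 0.32 and GLT1 (AT5G53460), a glutamate synthase, at 1.21 ± 0.14.

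Jasmonate genes were higher at 45 min than at 0 min, with 9 of 9 called (9 adjusted over the list alone), a median of 3.06 (3.06 with JAZ8 at its bound) and JAZ10 (AT5G13220) at 4.23 ± 0.33. JAZ8 was at least 11.7-fold higher, from 29 reads against 0 (7.29 without replicate 3 at 0 min and 7.72 without batch 3). LOX3 had 142 reads against 3, a ratio of 57.5 (95% counting interval 19.3 to 282). The ratio was 38.2 and 107 without replicate 4 or 3 at 0 min, and 112 and 32 without batch 3 or 4. In the touch and wound list 8 of 17 genes rose (9 adjusted over the list alone), with WRKY40 at 3.34 ± 0.39. Camera adjusted p was 3.14e-56 and 3.05e-10 for these lists (2.11e-08 and 0.00646 with an estimated correlation). Morning clock genes were lower, 5 of 9 called (6 adjusted over the list alone; adjusted p = 4.28e-07, and 0.00287 with an estimated correlation), CCA1 by -1.12 ± 0.14. Lateral root initiation genes were not called as a list (adjusted p = 0.0636, and 0.0396 with no filter on low counts), but 3 of 21 rose (4 adjusted over the list alone), among them LBD16 (AT2G42430), a transcription factor that acts in founder cell polarity, at 0.99 ± 0.28 (5.89 ± 1.28 to 12 ± 3.02 CPM, adjusted p = 0.0242). Its call was lost in a fit of the 8 libraries alone (adjusted p = 0.0541), and without replicate 3 or 4 at 0 min (0.0939 and 0.087) or replicate 2 or 4 at 45 min (0.0535 and 0.0702), and without batch 1, 3 or 4 (0.0509, 0.0695 and 0.217). The auxin carrier gene PIN3 (AT1G70940) rose by 0.93 ± 0.18, and PIN5 (AT5G16530) fell by 2.11 ± 0.23. MYR1 (AT5G18240) was at -3.31 ± 0.48 (-4.2 without replicate 3 at 45 min and -4.35 without batch 3) and AT1G04330 at -2.17 ± 0.22. AT5G61890 had 97 reads against 1, a ratio of 118 (95% counting interval 20.7 to 4700). The ratio was 78.2 and 73.2 without replicate 4 or 3 at 0 min and 68.2 and 62.2 without batch 3 or 4. Without replicate 1 at 0 min, which held the 1 read, or batch 1 it was at least 35.2 and 33. AT2G38240 rose by 5.27 ± 0.56 and AT5G62360 by 5.24 ± 0.62. The latter rose by 5.86 without replicate 2 at 0 min and 6.19 and 4.4 without batch 2 or 4.

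Smaller shifts were seen in 3 more lists at 45 min. Type-A response regulators were lower, 3 of 10 called (4 adjusted over the list alone; adjusted p = 0.0122, and 0.105 with an estimated correlation). ARR15 (AT1G74890) among them was at -2 ± 0.52 (-2.7 without replicate 4 at 45 min and -2.8 without batch 4), and lost its call in a fit of the 8 libraries alone (0.128), without replicate 2 at 45 min (adjusted p = 0.102) and without replicate 3 at 0 min (0.0611), and without batch 1, 2 or 3 (0.0698, 0.147 and 0.16). The 8 ribosome biogenesis genes all had positive values (median 0.34, 0 called and 1 adjusted over the list alone), and the list passed at adjusted p = 0.0196 but not with an estimated correlation (adjusted p = 0.171) or without replicate 4 of 1 mM at 45 min (0.148). In batches 1 to 4 its mean was -0.02, 0.16, 0.31 and 0.78. Marker lists of other cell types were at -0.11, 0.23, 0.59 and 0.7 for root tip, 0, -0.09, -0.12 and -0.87 for root hair, and 0.11, -0.19, -0.13 and -0.57 for endodermis in the same batches. Xylem markers were at 0.12, -0.34, -0.06 and 0.22, and the photosynthesis list at -0.56, 0.18, -0.57 and -1.1. Photosynthesis genes, fixed as markers of shoot tissue, had a median of -0.41 with 0 of 17 called and 0 adjusted over the list alone (camera adjusted p = 0.00586, and adjusted p = 0.117 with an estimated correlation); with no filter on low counts the list was not called (0.07). Over the whole transcriptome edgeR called 1311 genes, 885 higher and 426 lower. The count was 2193 with the batch as a block, 658 in a fit of the 8 libraries alone, 641 without replicate 3 and 857 without replicate 4.

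At 90 min the amino acid genes ASN1 (2.41 ± 0.31), GDH2 (AT5G07440) (1.51 ± 0.19) and GLT1 (1.21 ± 0.14) were higher than at 0 min. They belong to the ammonium assimilation list, in which 4 of 10 rose and 3 fell (5 and 3 adjusted over the list alone). That list missed the threshold at adjusted p = 0.0507 and passed it with the batch as a block (0.0147). Nitrate response regulators were higher, with 9 of 24 up and 2 down (10 and 2 adjusted over the list alone; adjusted p = 4.01e-08, and 0.00513 with an estimated correlation), led by bZIP1 at 3.05 ± 0.46, BT2 at 2.87 ± 0.37 and BT1 at 2.86 ± 0.37. The low-nitrogen list was lower, 5 of 10 down and 1 up (5 and 1 adjusted over the list alone; adjusted p = 0.000281, and 0.0102 with an estimated correlation). In it the high-affinity nitrate transporter gene NRT2.5 (AT1G12940) had 1 read against 43 at 0 min, a 49.7-fold lower level (95% counting interval 8.45 to 2010), and NRT2.4 (AT5G60770) was at -1.40 ± 0.30. For NRT2.5 the ratio was 32.4 without replicate 4 at 90 min and 28.4 without batch 4. Without replicate 2 at 90 min, which held the 1 read, or batch 2 it was at least 12.5 and 13.2. Nitrate reduction genes were not called as a list (adjusted p = 0.172): 1 of 12 rose (5 adjusted over the list alone), AT1G64190, a 6-phosphogluconate dehydrogenase, at 0.58 ± 0.13. Class III glutaredoxins rose, 3 of 5 called (3 adjusted over the list alone; median 1.84, adjusted p = 0.00536, and 0.0324 with an estimated correlation), with AT4G15690 at 3.39 ± 0.62. Its family includes near-identical tandem copies, so the split of reads among them is uncertain.

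Jasmonate and touch and wound genes were higher at 90 min than at 0 min. All 9 jasmonate genes were called (9 adjusted over the list alone; median 2.08, and 2.08 with JAZ8 at its bound; adjusted p = 4.58e-25, and 2.75e-05 with an estimated correlation), with JAZ10 at 3.09 ± 0.33. JAZ8 was at least 6.93-fold higher from 24 reads against 0. That bound was 4.6 and 4.3 without replicate 4 or 3 at 0 min and 3.65 and 4.41 without batch 3 or 4. LOX3 had 75 reads against 3 (ratio 21.6, 95% counting interval 7.13 to 107). The ratio was 40.3 without replicate 3 at 0 min and 35.2 without batch 3. In the touch and wound list 5 of 17 were called (7 adjusted over the list alone; adjusted p = 8.65e-06, and 0.0495 with an estimated correlation), with ERF2 (AT5G47220) at 2.04 ± 0.25. Morning clock genes were lower, 6 of 9 called (1 up and 6 down adjusted over the list alone; adjusted p = 2.66e-15, and 7.88e-06 with an estimated correlation), with LHY (AT1G01060) at -2.32 ± 0.21 and CCA1 at -2.05 ± 0.15. The hypoxia-associated genes ADH1 (AT1G77120) (1.51 ± 0.31) and HRE1 (AT1G72360) (1.17 ± 0.23) rose in a low-oxygen list that was not called (2 of 7 up, and 2 up and 3 down adjusted over the list alone; adjusted p = 0.785). Among all genes the largest named rises were AT5G62360 at 5.95 ± 0.57 (6.57 without replicate 2 at 0 min, and 6.64 and 5.31 without batch 2 or 4) and AT2G38240 at 5.61 ± 0.54, while AT1G64500 was at -2.28 ± 0.32. edgeR called 1340 genes, 926 higher and 414 lower. With the batch as a block there were 2214, without replicate 2 there were 803 and without replicate 3 there were 751.

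At 180 min morning clock genes were lower and evening clock genes higher than at 0 min. Of 9 morning genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), LHY by -3.45 ± 0.23 and CCA1 by -3 ± 0.16, the latter from 71.3 ± 1.76 to 8.71 ± 1.91 CPM. Of 10 evening genes 6 rose (8 rose and 1 fell adjusted over the list alone), among them PRR5 (AT5G24470) at 2.93 ± 0.68, PRR3 (AT5G60100) at 1.74 ± 0.39 and GRP7 (AT2G21660) at 1.1 ± 0.14. PRR5 was at 2.32 and 3.55 without replicate 3 or 4 at 0 min, and at 2.31 without batch 3, where it lost its call (adjusted p = 0.0874). PRR3 lost its call without replicate 4 (adjusted p = 0.102). Camera adjusted p was 2.12e-31 for the morning and 4.14e-06 for the evening list (4.19e-09 and 0.000555 with an estimated correlation). The jasmonate list was higher, with 3 of 9 called (4 adjusted over the list alone), a median of 0.64 (0.51 with JAZ8, at 4 reads against 0, set to its bound) and adjusted p = 3.74e-05 (0.0486 with an estimated correlation). JAZ10 was at 1.43 ± 0.35 and lost its call without replicate 3 (0.0765) or 4 (0.0626). The touch and wound list was not called (adjusted p = 0.609), with 3 of 17 up (3 up and 1 down adjusted over the list alone), CML38 (AT1G76650) at 1.74 ± 0.31 among them.

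Nitrate response regulators were higher at 180 min than at 0 min, 9 of 24 up and 2 down (10 and 2 adjusted over the list alone; adjusted p = 5.07e-08, and 0.00542 with an estimated correlation), with bZIP1 at 2.97 ± 0.47. Ammonium assimilation genes were called, 5 of 10 up and 2 down (5 and 3 adjusted over the list alone; adjusted p = 0.0144, and 0.0486 with an estimated correlation), with ASN1 at 1.79 ± 0.32. The nitrate reduction list had 4 of 12 up (6 up and 1 down adjusted over the list alone; adjusted p = 0.00847, and adjusted p = 0.325 with an estimated correlation), NIA1 at 1.13 ± 0.21 and NIR1 at 0.69 ± 0.15. Low-nitrogen genes were lower, 3 of 10 down and 1 up (4 and 1 adjusted over the list alone; adjusted p = 0.000443, and 0.0121 with an estimated correlation). NRT2.5 was at -2.64 ± 0.65 there, a call lost without replicate 3 (0.0735) or 4 (0.0859), and NRT2.4 at -2.08 ± 0.33. The nitrate transport list was not called (2 of 13 up, 3 adjusted over the list alone; adjusted p = 0.199), although NPF6.3 (AT1G12110), the dual-affinity transporter and nitrate sensor, rose by 0.87 ± 0.14. Glutaredoxins were higher (3 of 5, and 3 adjusted over the list alone; adjusted p = 0.0163, and 0.0486 with an estimated correlation), with the same limit on reads shared by copies, as were low-oxygen genes (2 of 7, and 3 adjusted over the list alone; adjusted p = 0.0188, and 0.0486 with an estimated correlation), ADH1 at 1.66 ± 0.31.

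Cytokinin synthesis and breakdown genes were higher at 180 min (2 of 9, and 3 adjusted over the list alone), with CYP735A2 (AT1G67110), which makes trans-zeatin forms, at 1.65 ± 0.25. The list's adjusted p was 0.0356, and 0.0506 with an estimated correlation, 0.0606 with the batch as a block and 0.055 with no filter on low counts. The ammonium call of that time was also lost with no filter (adjusted p = 0.0683). ARR7 (AT1G19050) rose by 1.01 ± 0.21 within a type-A list that was not called (1 of 10 up, and 1 up and 2 down adjusted over the list alone; adjusted p = 0.991). AT3G55677 was at -2.73 ± 0.51 and the iron transporter gene IRT1 (AT4G19690) at -2.70 ± 0.40. IRT1 was at -4.16 without replicate 4 at 180 min and -3.98 without batch 4. AT4G21870 was at 4.22 ± 0.44 and scpl30 (AT4G15100) at 4.21 ± 0.41 (4.82 without replicate 2 at 0 min and 4.8 without batch 2). edgeR called 1414 genes, 904 higher and 510 lower. The count was 2287 with the batch as a block, 869 without replicate 2 and 736 without replicate 3.

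**Figure D1:**
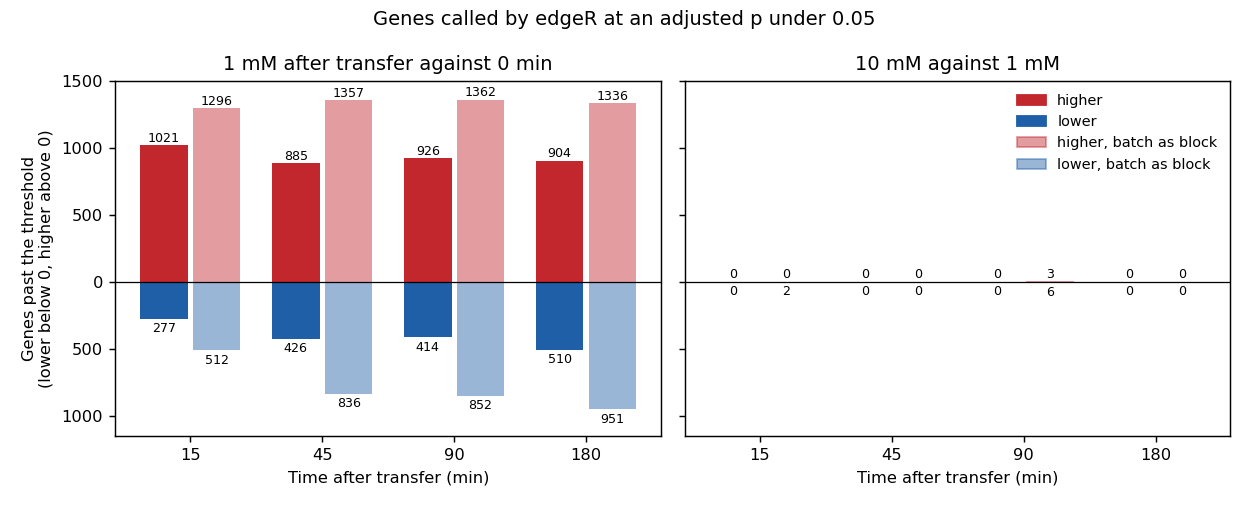
Number of genes called by edgeR at an adjusted p of 0.05 at each time (evenly spaced, not to scale), higher and lower, for 1 mM against 0 min and for 10 mM against 1 mM, without and with the batch as a block. Counts for 1 mM against 0 min run from 1298 to 1414 without the block, and for 10 mM against 1 mM they are 0 without the block and 2, 0, 9 and 0 with it.

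Between 10 mM and 1 mM at 15 min, the clearest difference was in jasmonate genes. All 9 measured genes of that list had lower values in 10 mM, from -0.83 to -0.25 with a median of -0.47: JAZ10 was at 55.8 ± 18.7 CPM in 10 mM and 97.8 ± 18.2 CPM in 1 mM (-0.83 ± 0.26), and OPR3 (AT2G06050), an enzyme of jasmonate synthesis, at -0.47 ± 0.13. Adjusted over the list alone 3 were lower, and over all genes 0. The list was lower by camera (adjusted p = 9.95e-12, and 0.00695 with an estimated correlation), and its mean difference was -0.86, -0.52, -0.11 and -0.58 in replicates 1 to 4. Of the 35 splits of these 8 libraries, 2 gave the list a camera p as small, the real one included. The touch and wound list was also lower by camera (mean -0.16, 5 of 17 positive, 1 lower adjusted over the list alone; adjusted p = 0.00522, and adjusted p = 0.325 with an estimated correlation), though its mean was -0.79, -0.24, 0.25 and -0.03 in the 4 batches. Nitrate reduction genes were higher by camera (mean 0.17, 10 of 12 positive, 0 called adjusted over the list alone; adjusted p = 0.00107, and adjusted p = 0.325 with an estimated correlation). Type-A response regulators were too (mean 0.12, 7 of 10 positive, 0 adjusted over the list alone). Camera gave adjusted p = 0.0352 for them, and adjusted p = 0.29 with an estimated correlation. In replicates 1 to 4 their mean difference was -0.14, 0.21, 0 and 0.22. For nitrate reduction genes it was 0.44, 0.09, 0.03 and 0.17.

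No single gene was called at 15 min by edgeR. Of 18768 genes, 486 had an unadjusted p under 0.05, where 938 would be expected by chance, and DESeq2 called 0 with 462. The blocked fit gave 848 such genes. Without the block, differences between batches count as spread, so a number below 938 is not evidence of no KNO3 effect. With the batch as a block 2 genes were called, both lower in 10 mM and both named after their values were seen: AT2G02680 at -1.14 (adjusted p = 0.0133) and JAZ10 at -0.89 (adjusted p = 0.0182). Without replicate 1 the fit with no block called AT2G02680 (-1.32, adjusted p = 0.0202). NIA1 was at 0.28 ± 0.21 and NIR1 at 0.19 ± 0.15, NRT2.1 (AT1G08090) at 0.03 ± 0.18, NPF6.3 at 0.17 ± 0.14, HRS1 (AT1G13300) at 0.10 ± 0.18, LBD37 (AT5G67420) at 0.10 ± 0.13 and NRT2.5 at 0.16 ± 0.49. Of the lateral root genes, GATA23 (AT5G26930) was at -0.70 ± 0.39, LBD16 at -0.42 ± 0.30, LBD29 (AT3G58190) at -0.49 ± 0.44, ARF7 (AT5G20730) at 0.05 ± 0.24, ARF19 (AT1G19220) at -0.06 ± 0.25 and IAA14 (AT4G14550) at 0.03 ± 0.27.

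At 45 min the type-A response regulators stood higher in 10 mM than in 1 mM. All 10 measured had positive values, with a mean of 0.30, and 2 were higher adjusted over the list alone (0 over all genes): ARR5 (AT3G48100) was at 58.0 ± 8.94 CPM in 10 mM and 43.8 ± 3.76 CPM in 1 mM (0.39 ± 0.13) and ARR8 (AT2G41310) was at 0.36 ± 0.13. Camera gave adjusted p = 0.00198 for the list, and adjusted p = 0.0998 with an estimated correlation. Nitrate response regulators were higher (mean 0.10, 19 of 24 positive, 0 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.464 with an estimated correlation), and ribosome biogenesis genes lower (mean -0.24, 0 of 8 positive, 0 adjusted over the list alone; adjusted p = 0.00676, and adjusted p = 0.343 with an estimated correlation). Neither list was called without replicate 4 of 1 mM at 45 min, the library apart from its group (0.477 and 0.274), and the regulators were not called without the genes that lack a reference symbol (0.0596). In batch 4, which holds that library, the mean was -0.7 for ribosome biogenesis, -0.31 for root tip, -0.08 for xylem, 0.25 for endodermis, 0.67 for root hair and 0.89 for photosynthesis genes. Nitrate reduction genes were not called (mean 0.10, adjusted p = 0.221) but were without such genes (0.00779), and low-oxygen genes were not called (adjusted p = 0.221) but were with no filter on low counts (0.0413).

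At 45 min edgeR called 0 genes, with 915 at an unadjusted p under 0.05, and DESeq2 called 0 with 947. The batch as a block also gave 0, with 1485 at an unadjusted p under 0.05, where 938 would be expected by chance. NIA1 was at 0.20 ± 0.21, NIR1 at 0.17 ± 0.15, NRT2.1 at 0.28 ± 0.18, NPF6.3 at 0.06 ± 0.14, HRS1 at 0.15 ± 0.17 and LBD37 at 0.28 ± 0.13. LBD37 in replicate 4 of 1 mM was at 110.7 CPM, below the other 3 libraries of its group. That library was also the lowest of its group for NIA1, NIR1 (664.4 CPM), NRT2.1 (236.3 CPM), NPF6.3, HRS1, GATA23, LBD29 and IAA14 (4.232 CPM). It was the highest for LBD16 (16.22 CPM), ARF19 and NRT2.5, and neither for ARF7. The differences given here therefore rest in part on that library. NRT2.5 was at -1.95 ± 0.60, from 11 reads in 10 mM and 33 in 1 mM. GATA23 was at -0.02 ± 0.44, LBD16 at -0.38 ± 0.27, LBD29 at 0.34 ± 0.44, ARF7 at -0.19 ± 0.25, ARF19 at 0.07 ± 0.25 and IAA14 at 0.11 ± 0.27.

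At 90 min the nitrate reduction genes were higher in 10 mM. All 12 had positive values, with a median of 0.28 and a mean of 0.32: NIA1 was at 271 ± 36.1 CPM in 10 mM and 172 ± 35.5 CPM in 1 mM (0.66 ± 0.21, 1.58-fold, 95% confidence interval 0.24 to 1.08 on the log2 scale), NIR1 at 759 ± 36.9 and 569 ± 41.6 CPM (0.42 ± 0.15), and G6PD3 at 0.57 ± 0.19. Adjusted over the list alone 3 were higher, and over all genes 0. The list was higher by camera (adjusted p = 1.23e-08, and adjusted p = 0.104 with an estimated correlation), with means of 0.31, 0.42, 0.18 and 0.38 in the 4 batches. Nitrate response regulators were higher (mean 0.15, 18 of 24 positive, 2 adjusted over the list alone; adjusted p = 0.0315, and adjusted p = 0.236 with an estimated correlation), with NAC4 (AT5G07680) at 1.08 ± 0.31 and HRS1, a NIGT1-type repressor, at 79.2 ± 6.11 CPM in 10 mM and 56.3 ± 12.4 CPM in 1 mM (0.51 ± 0.17). Type-A response regulators were called (median 0.21, mean 0.05, 7 of 10 positive, 2 adjusted over the list alone; adjusted p = 0.0362, and adjusted p = 0.202 with an estimated correlation), but not with the batch as a block (0.0539). Without genes that lack a reference symbol neither list was called (0.0682 for the nitrate regulators and 0.0521 for the type-A list).

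No gene reached the threshold at 90 min in edgeR without the block, with 873 at an unadjusted p under 0.05, or in DESeq2, with 876. The blocked fit had 1595 at such a p, where 938 would be expected by chance. With the batch as a block 9 genes were called, 3 higher and 6 lower, each in the same direction in 4 of 4 batches and named after their values were seen. ABF3 (AT4G34000), a transcription factor of the abscisic acid response, was at 0.54 (adjusted p = 0.0316), and ERD5 (AT3G30775), known as a proline dehydrogenase, at -0.83 (adjusted p = 0.00776). The other 7 were AAE3 (AT3G48990) and AT3G56740, higher, and AT3G46700, MIOX2 (AT2G19800), UMAMIT17 (AT4G08300), AT1G21050 and AT4G32480, lower. NRT2.1 was at 0.29 ± 0.18, NPF6.3 at 0.17 ± 0.14 and LBD37 at 0.16 ± 0.13, while NRT2.5 had 2 and 1 reads, too few for a fold. GATA23 was at -0.87 ± 0.46, LBD16 at -0.25 ± 0.27, LBD29 at 0.31 ± 0.45, ARF7 at 0.38 ± 0.24, ARF19 at -0.03 ± 0.24 and IAA14 at -0.25 ± 0.26.

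At 180 min all 12 nitrate reduction genes again had positive values in 10 mM against 1 mM, with a median of 0.19 and a mean of 0.22. NIA1 was at 384 ± 120 CPM in 10 mM and 255 ± 49.3 CPM in 1 mM (0.59 ± 0.21), NIA2 (AT1G37130) at 0.27 ± 0.15 and NIR1 at 0.19 ± 0.15, with 0 called over all genes and 0 adjusted over the list alone. The list was higher by camera (adjusted p = 7.7e-06, and adjusted p = 0.396 with an estimated correlation), with means of 0.26, 0.16, 0.35 and 0.12 in the 4 batches. Glutaredoxins, not called here (adjusted p = 0.19), were called with no filter on low counts (0.0244). HRS1 was at 0.35 ± 0.17, NRT2.1 at 0.04 ± 0.18, NPF6.3 at 0.11 ± 0.14 and LBD37 at 0.03 ± 0.13. NRT2.5 had 2 reads in 10 mM and 6 in 1 mM, a ratio of 3.48 lower (95% counting interval 0.621 to 35.2). GATA23 was at -0.41 ± 0.46, LBD16 at 0.09 ± 0.27, LBD29 at -0.03 ± 0.44, ARF7 at 0.48 ± 0.24, ARF19 at 0.05 ± 0.25 and IAA14 at -0.03 ± 0.27. edgeR called 0 genes, with 369 at an unadjusted p under 0.05, and DESeq2 called 0 with 363. The batch as a block gave 0, with 729 at an unadjusted p under 0.05.

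**Figure D2:**
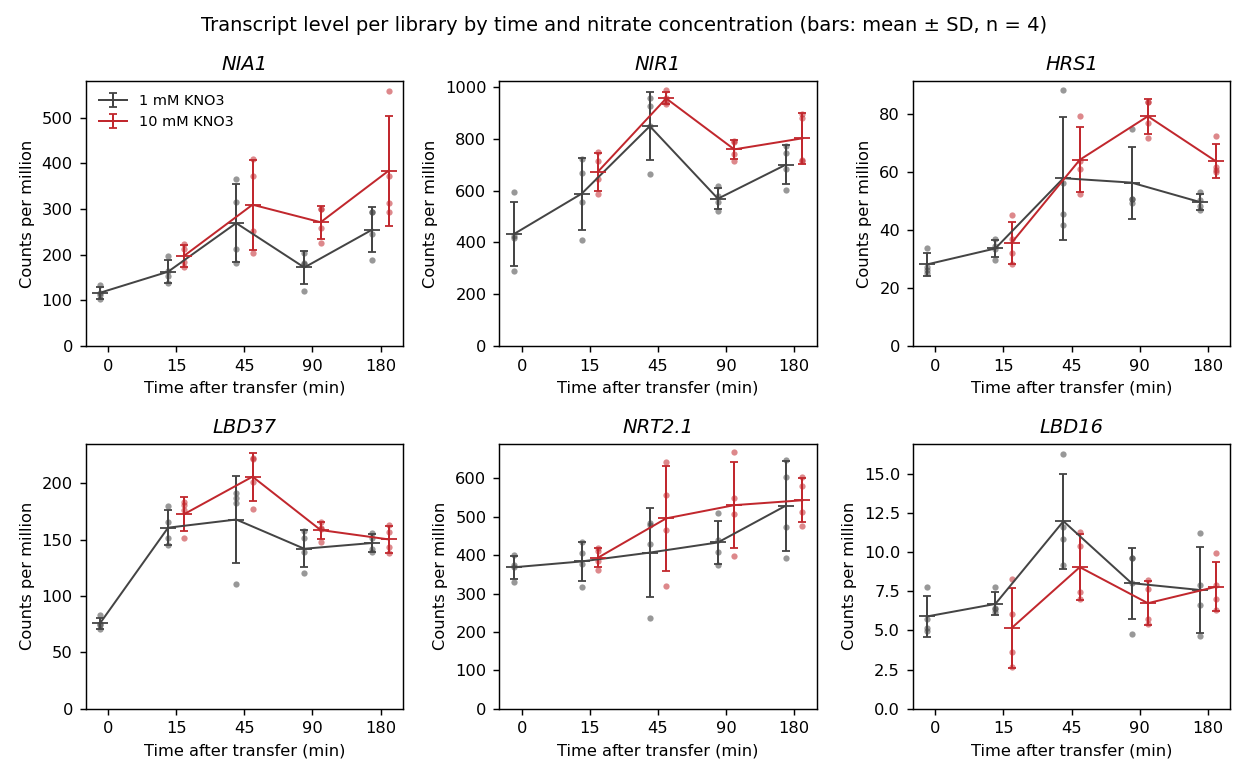
CPM of NIA1, NIR1, HRS1, LBD37, NRT2.1 and LBD16 in each library by time (evenly spaced, not to scale) in 1 mM and 10 mM, with the mean ± SD of 4 libraries. NIA1 at 90 min is at 271 ± 36.1 CPM in 10 mM and 172 ± 35.5 CPM in 1 mM, and no gene shown is called between the concentrations at a single time.

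Lists for lateral root initiation and auxin were not called between 10 mM and 1 mM. Adjusted p at 15, 45, 90 and 180 min was 0.888, 0.77, 0.104 and 0.694 for the 21 lateral root initiation genes, 0.771, 0.648, 0.966 and 0.685 for 19 early auxin genes and 0.125, 0.593, 0.21 and 0.694 for 18 genes of auxin transport, synthesis and perception. At 90 min the mean of the lateral root initiation list was -0.29, -0.27, -0.11 and -0.15 in the 4 batches, and that of the auxin transport list -0.1, -0.14, -0.16 and -0.04. Neither was called with the batch as a block (adjusted p = 0.167 and 0.219). Of 25 lists, 3, 3, 9 and 4 had 4 rounded batch means on 1 side of 0 at 15, 45, 90 and 180 min. Chance gives this in 12.5% of lists. At 45 min the nitrate response regulators also had 4 means above 0 before rounding, the lowest of which rounds to 0. Nitrate transport (0.479, 0.966, 0.21 and 0.653), ammonium assimilation (0.771, 0.39, 0.0788 and 0.653) and low-nitrogen genes (0.349, 0.593, 0.979 and 0.549) were not called either. Adjusted over the list alone, 1 lateral root initiation gene was higher at 15 min, 3 ammonium assimilation genes were higher at 90 min, with GLT1 at 0.40 ± 0.14 and ASN2 (AT5G65010) at 0.60 ± 0.22, and 1 low-nitrogen gene was lower at 45 min. For cytokinin synthesis and breakdown the values were 0.743, 0.966, 0.281 and 0.549, for the cell cycle 0.771, 0.727, 0.901 and 0.694, for phosphate starvation 0.821, 0.966, 0.92 and 0.549, and for potassium transport 0.974, 0.761, 0.714 and 0.19. Morning clock genes (0.112, 0.648, 0.36 and 0.241; 1 higher at 90 min adjusted over the list alone) and evening clock genes (0.743, 0.617, 0.178 and 0.694) were not called between the concentrations. Low-oxygen genes were not called at any of the 4 times (0.479, 0.221, 0.191 and 0.694), with 0 of 7 lower adjusted over the list alone. Their mean was -0.16, -0.21, -0.27 and -0.03 in turn. In the 4 batches it was -0.01, -0.23, -0.03 and -0.21 at 15 min and -0.43, -0.34, -0.35 and -0.04 at 90 min. At times not given above, adjusted p was 0.966, 0.619 and 0.694 for jasmonate and 0.761, 0.218 and 0.694 for touch and wound genes at 45, 90 and 180 min. It was 0.398 and 0.19 for nitrate response regulators at 15 and 180 min, and 0.549 for type-A regulators at 180 min. Values were 0.398, 0.281 and 0.685 for ribosome biogenesis genes at 15, 90 and 180 min and 0.342, 0.761 and 0.265 for glutaredoxins at 15, 45 and 90 min.

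Marker lists for other tissues gave no call between 10 mM and 1 mM. In the same order of times, adjusted p was 0.459, 0.055, 0.979 and 0.694 for photosynthesis genes, 0.208, 0.761, 0.21 and 0.694 for root hair, 0.771, 0.966, 0.21 and 0.19 for xylem, 0.637, 0.761, 0.471 and 0.685 for endodermis and 0.342, 0.593, 0.619 and 0.694 for root tip markers. Each of these 5 lists had 0 genes called, and 0 adjusted over the list alone, at any of the 4 times. In 1 mM against 0 min, 1 of 17 photosynthesis genes was lower at 90 min (0 adjusted over the list alone; list adjusted p = 0.431), PSBO1 (AT5G66570) at -0.63 ± 0.20 (adjusted p = 0.0498). Its call was lost in 13 of 18 alternatives, among them leaving out any 1 of the 8 libraries compared (adjusted p from 0.0519 to 0.18), any batch (0.0854 to 0.185) and no filter on low counts (0.0616). Root tip markers had 2 of 8 higher at 45 min (2 adjusted over the list alone; adjusted p = 0.0636, and 0.0249 with no filter on low counts) and 1 higher and 1 lower at 90 min (1 and 1 adjusted over the list alone; 0.785). Of 6 root hair markers 1 was lower at 90 min (2 adjusted over the list alone; 0.191), and of 7 endodermis markers 1 was lower at 180 min (1 adjusted over the list alone; 0.455). None of these root tip, root hair and endodermis gene calls held without each library and batch in turn. Adjusted over the list alone, 1 root hair marker was also lower at 45 min and 1 at 180 min. No xylem marker of 6 was called at any of the 4 times against 0 min, or adjusted over the list alone.

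**Figure D3:**
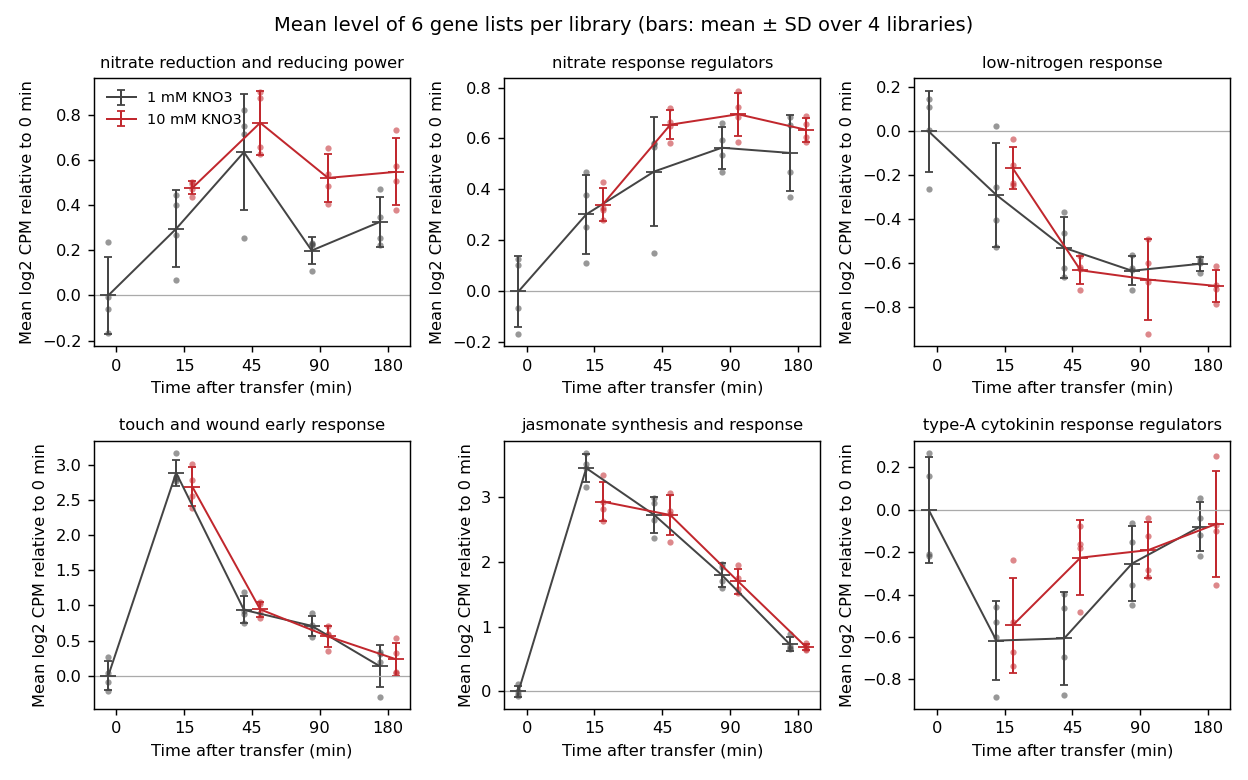
Mean moderated log2 CPM (prior count 2) of 6 gene lists by time (evenly spaced, not to scale), relative to 0 min, in 1 mM and 10 mM. Jasmonate genes are lower in 10 mM at 15 min by a mean of 0.48 in the fitted values and nitrate reduction genes higher at 90 min by a mean of 0.32.

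The joint test of the 4 concentration differences and the test that they differ between times called 0 genes in edgeR without a block, while an average over the 4 times, added after the data were seen, called 3. For any difference at 4 times edgeR called 0 genes, with 522 at an unadjusted p under 0.05. The batch as a block gave 16, with 1325 at such a p, and DESeq2 gave 1, ABF3 (adjusted p = 0.00267), named after its value was seen. For a concentration effect that differs between times the batch as a block gave 0 genes, with 1047 at an unadjusted p under 0.05. Without it edgeR called 0, with 405 at such a p, and DESeq2 called 0 with 428. The gene with the smallest p in that edgeR test was AT3G02480, a late embryogenesis abundant protein gene (adjusted p = 1), with differences of 0.07 ± 0.54, -1.88 ± 0.51, 1.74 ± 0.56 and -0.53 ± 0.50 at 15, 45, 90 and 180 min. LEP (AT5G13910), sixth by p in edgeR, was at 0.65 ± 0.15 at 15 min and -0.13 ± 0.14 at 180 min (adjusted p = 1).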

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

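The tests of spread, of swapped labels, of a response already engaged, of weaker handling, of organelle transcripts and of shoot tissue were chosen only after the result was seen.

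In 20 of 153 sets of 4 values, 1 set for each group and measure, 1 library lay far from the other 3. Chance gives about 1 set in 20 for independent, normally spread values. These sets share libraries and some hold very low counts, so that rate is only a rough guide. Replicate 1 had the lowest median correlation with its group mates at 0 min (0.9509), in 10 mM at 15 min (0.955), 45 min (0.9582), 90 min (0.9557) and 180 min (0.9698), and in 1 mM at 90 min (0.9612) and 180 min (0.9489). It also had few detected genes in 1 mM at 15 min (19794, others 21243 to 21507) and in 10 mM at 45 min (20092, others 21307 to 21541). Replicate 4 of 1 mM at 45 min had a median correlation of 0.9091 (others 0.9419 to 0.9485) and LBD37 at 110.7 CPM (others 182.3 to 191.5). HRS1 in replicate 1 stood at 74.91 CPM in 1 mM at 90 min and 72.33 CPM in 10 mM at 180 min, and IAA14 in replicate 1 of 1 mM at 90 min at 31.69 CPM. LBD29 was at 1.035 CPM in replicate 1 at 0 min, LBD16 at 7.777 CPM in replicate 3 of 1 mM at 15 min, and ARF19 at 6.205 CPM in replicate 4 of 10 mM at 180 min. NRT2.5 was at 0.1921 CPM in replicate 2 of 1 mM and 0.2661 CPM in replicate 4 of 10 mM at 90 min, with 0 in the other libraries of each group, and at 0.8004 CPM in replicate 1 of 1 mM at 180 min.

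The library of 1 mM at 45 min, replicate 4, stood apart from its group. Group mates thinned to its total count correlated with each other at 0.933 or more, above its highest correlation with them, 0.924, which argues against low depth as the whole cause. Over nuclear genes alone its median correlation was 0.914, below the lowest of its mates, 0.943, which argues against organelle transcripts. Its photosynthesis genes summed to 99.4 CPM, against 106 to 236 in the other 35 libraries, which argues against shoot tissue. No biological explanation was tested.

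No gene was called between 10 mM and 1 mM at a single time without the block. The median standard error was at most 1.002 times that of the comparison with 0 min, which called at least 1298 genes. Both comparisons come from the same fit, with a spread per gene shared by all groups, so similar standard errors are built in. The ratio therefore cannot tell whether spread or depth hid changes. In the simulated test at 90 min without the block, 90.9% of 66 genes changed 4-fold were found. Many genes were changed at once there, which eases the adjusted threshold. Where few genes change, the share found can be lower. With the batch as a block the biological coefficient of variation was 12.1%, against 17% without it. The blocked counts at 15, 45, 90 and 180 min were 2, 0, 9 and 0. The nitrate reduction list was higher in 10 mM in 15 of 16 pairs of batch and time, which argues against labels swapped within many pairs. It cannot show a swap in a few pairs, since some differences were near 0, such as 0.03 in batch 3 at 15 min. A candidate explanation is that the nitrate response was already engaged on fresh 1 mM plates: the same list was higher in 1 mM than at 0 min at 45 min (adjusted p = 0.0079 with an estimated correlation), but missed the threshold at 15, 90 and 180 min (0.638, 0.609 and 0.325). With an estimated correlation this bears on 45 min alone for that list. At the preset correlation the list was also called higher than at 0 min at 15 and 180 min, but not at 90 min. By camera with an estimated correlation, nitrate response regulators were higher than at 0 min at 45, 90 and 180 min (adjusted p = 0.00646, 0.00513 and 0.00542). Low-nitrogen genes were lower at those times (0.00646, 0.0102 and 0.0121). At 15 min the regulators missed the threshold (0.334), as did low-nitrogen genes at the preset correlation (0.0513). Handling and time of day differ in all these comparisons, so the explanation stays open. So do changes of 1.5-fold, of which the simulated test at 90 min found 18.2%.

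Jasmonate genes were lower in 10 mM than in 1 mM at 15 min. Their difference between the concentrations at 45, 90 and 180 min was less negative than at 15 min (adjusted p = 0.000808, 0.00127 and 0.00127 over 150 tests of list and time pairs, and 0.655 for each with an estimated correlation). A single batch is argued against: all 4 batch means were below 0, and leaving out 1 batch moved the mean by at most 1.28 times. A weaker handling response in the 10 mM plates could account for it, but the touch list lost 0.442 times the share of its rise that the jasmonate list lost, and its batch means, from -0.79 to 0.25, lie on both sides of the -0.36 expected. That explanation and an effect of KNO3 itself cannot be told apart, because the touch values spread too far between batches.

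Ribosome biogenesis genes differed between 45 and 15 min in their response to 10 mM (adjusted p = 0.0176 over 150 tests, and adjusted p = 0.655 with an estimated correlation). Their mean difference at 45 min was -0.18, 0.01, -0.07 and -0.7 in batches 1 to 4, and batch 4 there holds the library of 1 mM that stood apart from its group. In that batch the marker lists were at -0.31 for root tip, -0.08 for xylem, 0.25 for endodermis, 0.67 for root hair and 0.89 for photosynthesis genes.

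Chance was tested with other splits of the same libraries. For 1 mM against 0 min, 1 of 35 splits, the real one, called as many genes at each time (1298, 1311, 1340 and 1414). The highest other splits called 22, 167, 54 and 14, so the share is under 5% and argues against chance. Among the 8 splits that part all 4 pairs, as the real one does, the highest others called 4, 43, 54 and 11, and 8 splits are too few for a share under 5%. For 10 mM against 1 mM the real count was 0 at each time, which any split reaches (35 of 35), so these splits test nothing about chance. The highest others called 0, 121, 3 and 0, and 0 in those parting 4 pairs. The split with 121 genes at 45 min puts batches 1 and 2 of both concentrations against batches 3 and 4, parting no pair, so it points to a structure of the samples by batch, and the blocked count there was 0. Likewise the joint test of 4 times (real 0, highest other 19) and the test of differing effects (real 0, highest other 67) were reached by 40 of 40 draws, which tests nothing about chance. With the batch as a block and swaps within pairs, 1 of 40 draws, the real one, reached 16 genes for any time (highest other 0). The same held for 44 for the average (highest other 2) and 9 at 90 min (highest other 4). For any time and for the average this argues against chance. It does not exclude it, since 1 of 40 is the lowest share possible, the tests overlap without adjustment, and the average was added after the data were seen. At 90 min chance is not excluded, because swaps of 4 pairs at 1 time give only 8 distinct splits, too few for a share under 5%. At 15 min 2 of 40 reached the blocked count of 2, which does not exclude chance.

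For the list calls between 10 mM and 1 mM, the 35 splits include those that break the pairing by batch. The 8 that part all 4 pairs are too few for a share under 5%. With the pairing kept, chance is therefore not excluded for any of these lists. Only the 11 calls were examined in this way, of 100 tests of list and time. They were chosen by their real p, which favours a first rank, and ranks were not adjusted over the 100 tests. Over the 35 splits, the real camera p was the smallest for nitrate reduction at 90 min (4.92e-10, smallest other 1.75e-07), where the real mean of 0.32 was also the largest (largest other 0.24). The p was the smallest, but the size of the mean was not, for nitrate reduction at 180 min (3.08e-07, other 1.25e-06; mean as large in 2 of 35), type-A response regulators at 45 min (7.91e-05, other 8.24e-05; 5 of 35) and at 90 min (0.00434, other 0.00863; 25 of 35). These 4 calls were lost with an estimated correlation (adjusted p = 0.104, 0.396, 0.0998 and 0.202), and that of type-A regulators at 90 min also with the block (0.0539). Other splits gave a p as small for jasmonate genes at 15 min (3.98e-13, 2 of 35 as small, smallest other 1.88e-16), nitrate reduction at 15 min (8.57e-05, 2 of 35, 7.29e-05) and nitrate regulators at 90 min (0.00252, 2 of 35, 0.000718). The same holds for nitrate regulators at 45 min (0.00422, 3 of 35, 0.00181), type-A regulators at 15 min (0.00563, 5 of 35, 0.00153), ribosome genes at 45 min (0.000541, 5 of 35, 4.77e-05) and touch genes at 15 min (0.000627, 10 of 35, 8.67e-10). Among the 8 splits parting 4 pairs, the real one alone gave so small a p for nitrate reduction at 15, 90 and 180 min, jasmonate at 15 min, type-A regulators at 45 and 90 min and nitrate regulators at 90 min. There were 2 such splits for nitrate regulators and ribosome genes at 45 min and type-A regulators at 15 min, and 5 for touch genes at 15 min.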

How the results depend on the processing

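The fits without replicate 4 of 1 mM at 45 min, the list tests without members lacking a reference symbol, the estimated correlation in the blocked fit and the average over times were tests chosen only after the result was seen. Scaling by RLE changed no call among 230 named values and 200 list tests, and no scaling moved the median of all genes by 0.1. With the batch as a replicate block, 2 genes were called between 10 mM and 1 mM at 15 min, 9 at 90 min and 16 over any time, and against 0 min 2193 at 45 min, 2214 at 90 min and 2287 at 180 min, sharing 1311, 1340 and 1414 with the fit without it. The smaller spread with the block (12.1% against 17%) goes with this. Among lists the block ended 1 call between the concentrations and 1 against 0 min and added 3 against 0 min, all given with their values in the report, and it changed no other call. A fit of only the 8 libraries called 658 at 45 min against 0 min, and DESeq2 called 1 for any time; the cause was not tested. Leaving out 1 library or batch gave 0 to 1 genes for 10 mM against 1 mM at 15 min and 0 to 0 at 45, 90 and 180 min, over any time and for differing effects, and 0 to 5 for the average over times. Against 0 min it gave 883 to 1368 at 15 min, 641 to 1287 at 45 min, 751 to 1449 at 90 min and 736 to 1539 at 180 min, the lowest of each without replicate 3. Without replicate 4 of 1 mM at 45 min the counts against 0 min were 1368, 1173, 1449 and 1539. Of the 230 named values, DESeq2 ended 2 calls, no filter 10, a fit of only the 8 libraries 29 of 210, and the fits without replicates 1 to 4 ended 28, 46, 62 of 228, and 51. An estimated correlation ended 10 of 11 list calls between the concentrations and 7 of 31 against 0 min, and together with the block it ended 9 and 10 and added 2 against 0 min. List tests were not rerun without each library in turn. Depth was lowest in replicate 1, and low counts limit NRT2.5, GATA23 and LBD29. Every alternative fixed beforehand was run.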

Other observations

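The average over the 4 times, and the tests of risen and fallen genes other than those of 45 min tested at 90 min, were tests chosen only after the result was seen.

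Averaged over the 4 times, 3 genes differed between 10 mM and 1 mM without the block. ABF3, a transcription factor of the abscisic acid response, was higher by 0.33 ± 0.06, in 16 of 16 pairs of batch and time, AT5G52790 was higher by 0.51 ± 0.10, in 15 of 16, and AT2G43140 was at -0.68 ± 0.13, higher in 1 of 16 (adjusted p = 0.0334 each; 902 genes at an unadjusted p under 0.05). Without 1 library or batch the count ran from 0 to 5. It stayed within 1.5 times of 3 only without batch 1, without replicate 1 of 1 mM at 15 or 90 min or of 10 mM at 180 min, without replicate 2 of 1 mM at 45 min or of 10 mM at 90 min, and without replicate 4 of 1 mM at 45, 90 or 180 min or of 10 mM at 45 or 90 min. With the batch as a block 44 genes were called, 15 higher and 29 lower, and 1552 had an unadjusted p under 0.05. NIA1 was higher by 0.44 ± 0.08 (adjusted p = 0.00264, 15 of 16 pairs), and the type-A response regulator gene ARR8 by 0.29 ± 0.06 (adjusted p = 0.0165, 15 of 16). TMAC2 (AT3G02140) at -0.44 ± 0.07 (adjusted p = 0.000986) and ERD5 at -0.45 ± 0.07 (adjusted p = 0.00114) were higher in 1 of 16 pairs each, as was AT2G02680 at -0.60 ± 0.09 (adjusted p = 0.000986). The arabinogalactan protein genes AGP15 (AT5G11740) and AGP10 (AT4G09030) were at -0.27 ± 0.06 and -0.24 ± 0.05, both at adjusted p = 0.0165. HRE1 of the low-oxygen list, higher in 0 of 16 pairs, was at -0.36 ± 0.08 (adjusted p = 0.0367, and 0.653 without the block), and the mean of that list of 7 genes was above 0 in 2 of 16 pairs, while the list was not called at any of the 4 times. These genes were chosen after their values were seen.

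A hypothesis was that 10 mM extends the change seen after the move to 1 mM. Genes risen at 45 min (885) differed from all genes by -0.046 in 10 mM against 1 mM at 90 min, and 60 of 70 ordered splits gave a difference as large in the predicted direction (largest other 0.087). Genes fallen at 45 min (426) differed by 0.03, with 56 of 70 splits as low (largest other 0.06). Both values lie opposite to the prediction, which was not met by the bound written beforehand, 5% of splits. A share above 5% does not by itself exclude the hypothesis, so it stays undecided. In the family of 8 such tests, genes risen at 90 min (926) differed from all genes by -0.132 in 10 mM against 1 mM at 15 min. Of 35 splits 1 was as large (largest other 0.119), before any adjustment over the 8 tests. Genes fallen at 90 min (414) differed by 0.067, with 4 of 35. Both of these values also lie opposite to the hypothesis. The other 4 tests took the genes of 180 min for the difference at 45 min, -0.011 for risen (32 of 35 splits as large) and 0.025 for fallen (15 of 35), and those of 45 min for the difference at 180 min, 0.018 for risen (30 of 35) and 0.029 for fallen (17 of 35).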
